A study of Mus musculus with 4 samples.

How the data were processed

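Nuclei of the corpus callosum were profiled by droplet single-nucleus RNA sequencing in 4 libraries, 2 from wild-type (WT) mice and 2 from mice lacking lipocalin-type prostaglandin D synthase (L-PGDS, gene Ptgds; KO). All mice received cuprizone, so no group on normal diet was analysed here. Per the labels, the mice were male, on a C57BL/6 background and 11 weeks old, and were fed cuprizone for 5 weeks. The dose is given as 0.2% in the protocol and design text and as 0.5% in the treatment tag, and this was not resolved. Per the labels, nuclei were purified by fluorescence-activated sorting on DAPI and propidium iodide, which can itself set the share of each class. Groups and replicate numbers were taken from the labels. The labels give each library as a separate sample and do not state how many mice went into each, so p-values measure the spread between libraries.

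The authors deposited raw, unfiltered UMI counts per gene and barcode, made with Cell Ranger 7.1.0 per the file headers and on build mm10 per the submitters' processing notes. Whether intronic reads were counted was not given in the sources used here. The matrices hold 32285 genes. The 4 libraries held 55889924 and 66256061 UMIs in WT and 62734658 and 58722896 UMIs in KO, over 2136237, 2227639, 2228139 and 2060328 barcodes. The authors also deposited a table for immune nuclei with log2 fold changes and their standard errors, p-values and adjusted p-values, a Wald score, and normalized signal per library. Its columns are those DESeq2 writes, per the file headers, and every gene in it has a p-value under 0.05. It was used only for description, because it rests on the same 4 libraries and adds no further samples.

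Barcodes were kept as nuclei with at least 1132 UMIs, at least 300 genes and under 5% mitochondrial UMIs. The planned floor of 500 UMIs was raised by a rule fixed before the data were examined, to the highest inflection of the barcode rank curves (753 and 1000 UMIs in WT, 1132 and 948 in KO). Doublets were called per library with Scrublet as provided in scanpy, with an expected rate of 0.8% per 1000 nuclei, and its automatic threshold removed 207 and 179 nuclei in WT and 247 and 253 in KO. These were 3.35% and 2.66% of nuclei in WT and 4.16% and 4.19% in KO. Counts were normalized to 10000 per nucleus and log transformed, and 2000 variable genes, 30 principal components and 15 neighbours were used for Leiden clustering at resolution 0.8, with no integration between libraries. The 23985 nuclei fell into 31 clusters, and immune nuclei were clustered again into 8 sub-clusters. Barcodes with at least 100 and under 300 UMIs were read as empty droplets, which carry free RNA. Free RNA was left in the counts of the main results. An estimate of its share came from neuron markers in glial nuclei and from oligodendrocyte markers in neurons, and a subtraction of the empty-droplet profile was run as an alternative.

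Clusters were named from marker lists fixed before the data were examined. The scoring thresholds (a marker z score of at least 2, a ratio of 3 between glutamatergic and GABAergic genes, and at least 3 Snap25 counts per 10000 for neurons) were set after the clusters had been seen. A first neuron rule asked for 3 neuron markers in over 10% of nuclei. It named as neurons a cluster of 116 nuclei led by Vtn, Flt1, Dcn and Ptgds, and was replaced; that cluster was left unnamed and held 0.507% ± 0.112 of nuclei in WT and 0.463% ± 0.239 in KO (SD, n = 2 each). A second unnamed cluster of low-UMI barcodes, with neuron-marker levels above those of empty droplets, held 3.42% ± 0.951 in WT and 3.71% ± 0.526 in KO. One cluster of 198 inhibitory neuron nuclei scored highest on neuroblast markers, while the marker among its leading genes was the inhibitory marker Dlx6os1, and it stayed in that class. Another, of 388 inhibitory neuron nuclei, also scored highest on neuroblast markers, with a z score of 1.56, under the threshold of 2. The astrocyte-like cluster scored 3.59 on astrocyte markers and 3.12 on ependymal markers. Rebuilt names can differ from those of the study.

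Raw counts were summed per library and class, for classes with at least 30 nuclei in every library, and tested with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, default filterByExpr with Ptgds kept) in R 4.3.3. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, two-sided, and all fold changes are KO over WT. The 19 gene lists and 20 marker lists were fixed before the data were examined. Each list with at least 5 tested members was tested with camera (limma 3.58.1) at the preset correlation of 0.01, and again with an estimated correlation and with fry; list p-values were adjusted within a class. Shares of nuclei were compared by an exact permutation test over the 6 labelings of 4 libraries, whose smallest two-sided p is 0.33, and nuclei counts also with edgeR. The difference of the KO effect between 2 classes was tested with an interaction term in edgeR, with each library as a term of its own. Coordinates came from the GENCODE annotation of GRCm38 (mm10), matched by gene ID.

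The genes named were set by a rule fixed before the data were examined. It takes Ptgds first. For each main class (microglia, oligodendrocytes, OPCs, astrocytes and all immune nuclei) it then takes up to 10 genes per direction past the threshold with separated libraries, or the 5 with the smallest p where under 5 passed. For each list that passed or belongs to the class it takes up to 4 members with the smallest p. For further classes it takes up to 3 genes past the threshold per direction, and from the authors' table the 10 with the smallest adjusted p per direction. Predicted genes without a name are counted but passed over; where they are named, they were chosen after their values were seen.

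The alternatives were DESeq2 1.42.0, RLE instead of TMM scaling in edgeR, no filter on low counts, the replicate number as a block, UMI floors of 1000, 500 and 2000, doublets kept, mitochondrial UMIs under 1%, equal numbers of nuclei per library, Leiden resolution 1.6, and each library left out in turn. The floors of 500 and 2000, the subtraction of free RNA, the removal of mixed immune sub-clusters, the share among nuclei outside the neuron classes and the first naming rule were added after the data had been seen. The count test was tested on simulated data with 200 changed genes per class. It recovered 55.2%, 97.0% and 100% of genes changed by 2-fold, 4-fold and 8-fold in microglia (11935 genes), and 65.7%, 92.5% and 93.9% in oligodendrocytes (12480 genes). In OPCs it recovered 22.4%, 83.6% and 87.9% (7076 genes), in astrocytes 20.9%, 71.6% and 87.9% (5313 genes) and in all immune nuclei 59.7%, 95.5% and 98.5% (11959 genes). Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9.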

Results

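Cuprizone is a copper chelator that, given in the diet, kills oligodendrocytes and strips myelin from the corpus callosum, where microglia and astrocytes then become reactive. Ptgds encodes lipocalin-type prostaglandin D synthase, which makes prostaglandin D2. The comparison was between cuprizone-fed KO and WT mice, with 2 libraries per group. It asks how loss of L-PGDS alters the cells of the dissected tissue, given as corpus callosum. Neuron classes held 56.4% of nuclei in each group, and 1320 nuclei over all libraries were striatal projection neurons. Shares and gene changes are therefore not those of white matter alone. After filtering, 5969 and 6548 nuclei remained in WT and 5689 and 5779 in KO, with medians of 4646 and 4761.5 UMIs per nucleus in WT and 4830 and 4404 in KO. Median genes per nucleus were 2305 and 2352 in WT and 2334 and 2210 in KO.

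Ptgds (ENSMUSG00000015090; chromosome 2, 25466709 to 25470046, minus strand, mm10) was lower in KO libraries in every class that was tested. In oligodendrocyte-like nuclei it stood at 483 ± 281 CPM in WT and 22.1 ± 0.840 CPM in KO (SD, n = 2 each), a log2 fold change of −4.48 (SE 0.33, edgeR adjusted p = 7.78e-06). Without WT replicate 1 it was −3.725 and without WT replicate 2 −4.97. Microglia-like nuclei had 71.5 ± 25 CPM in WT and 1.98 ± 0.00854 in KO, a log2 fold change of −5.07 (SE 0.62, adjusted p = 2.32e-05). OPC-like nuclei held 20 counts in each WT library and 0 in both KO libraries, at least 11.6-fold lower against a floor of 3 counts over the group (adjusted p = 0.00202). Astrocyte-like nuclei held 23 and 17 counts in WT and 1 and 0 in KO (adjusted p = 0.0309). The log2 fold change was −4.64 (SE 0.82) in differentiating oligodendrocyte-like nuclei, −3.30 (SE 0.32) in excitatory and −2.70 (SE 0.39) in inhibitory neurons, and −4.05 (SE 0.29, adjusted p = 0.0308) over all nuclei. The highest level, 4849 ± 1582.5 CPM in WT and 347 ± 125 in KO, was in the unnamed cluster led by Vtn, Flt1 and Dcn, which was too small to test. Empty droplets held 555 ± 174 CPM of Ptgds in WT and 9.09 ± 2.35 in KO, above the WT level of microglia-like, OPC-like, astrocyte-like and neuron nuclei. The share of free RNA times the level in empty droplets gives 111 and 75.8 CPM of Ptgds in WT microglia-like nuclei, above the 89.2 and 53.9 CPM measured there. In OPC-like nuclei it gives 181 and 101 CPM against 44.0 and 42.8 CPM measured, and in astrocyte-like nuclei 114 and 82.9 CPM against 72.3 and 61.3 CPM. The level expected from free RNA was also above the measured level in all 4 neuron classes in WT, with 49.2 and 41.7 CPM against 21.5 and 13.7 CPM in excitatory and 47.6 and 42.5 CPM against 25.8 and 15.9 CPM in inhibitory neurons. An expected level above the whole measured level means that the estimate overstates free RNA in these WT nuclei. In KO OPC-like nuclei the expected level was 2.32 and 1.54 CPM, against 0 in both. In KO excitatory neurons it lay below the measured level, at 1.10 and 0.696 CPM against 2.14 and 1.37 CPM. How much of the difference free RNA carries in these classes was therefore not settled. A loss within microglia-like, OPC-like, astrocyte-like and neuron nuclei was not separated from free RNA. In WT oligodendrocyte-like nuclei the expected level was 109 and 66.2 CPM, against 681 and 285 CPM measured. At the estimated share, these values argue against free RNA as the source of the whole WT level there. Among 281 tested genes within 10 Mb of Ptgds, 7.12% had an unadjusted p under 0.05, against 6.77% of genes elsewhere (Fisher's exact test, two-sided p = 0.811). After subtraction of the empty-droplet profile Ptgds was called in no class. Oligodendrocyte-like nuclei then kept 1694 and 737 counts in WT and 61 and 46 in KO (−4.25, SE 0.44, adjusted p = 0.197; range over its 16 alternatives 1.03e-109 to 0.197), and differentiating oligodendrocyte-like nuclei were at −3.71 (SE 0.96, adjusted p = 0.202). No counts were left in microglia-like, OPC-like and astrocyte-like nuclei. In neuron classes none were left in WT, so that the direction turned, with 19 and 11 counts in KO excitatory neurons (adjusted p = 0.763). Where no WT counts were left, the overstated free RNA fixed that outcome, which does not test a loss in those classes. Where Ptgds was tested, its call was kept in 13 of 15 alternatives in OPC-like and 9 of 15 in astrocyte-like nuclei.

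**Figure D1:**
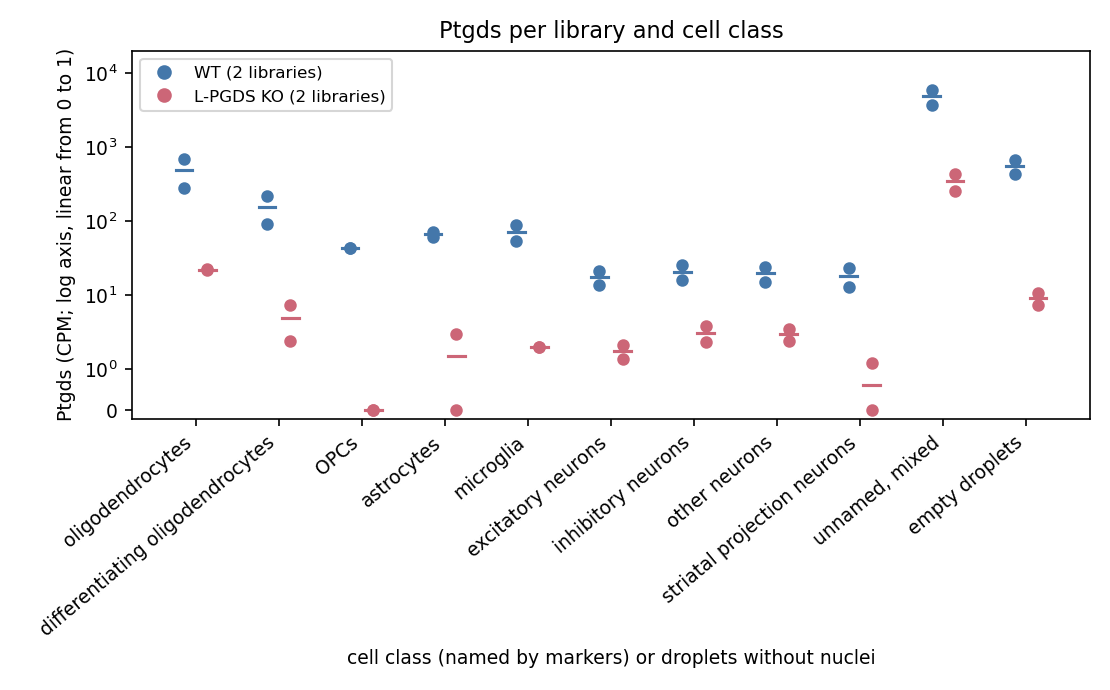
Ptgds level in CPM (symmetric log axis) by class of nuclei and in empty droplets, in WT and KO libraries. Points are libraries and short lines are group means. KO libraries lie below WT libraries in each class shown, with 483 against 22.1 CPM in oligodendrocyte-like nuclei.

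Microglia-like nuclei made up a larger share, and oligodendrocyte-like nuclei a smaller share, of both KO libraries than of either WT library. Microglia-like nuclei were 10.95% ± 1.98 of nuclei in WT and 14.5% ± 0.901 in KO, a difference of 3.53 percentage points (n = 2 each, exact permutation p = 0.33). Oligodendrocyte-like nuclei were 24.3% ± 1.59 in WT and 20.4% ± 1.13 in KO, a difference of −3.87 points (n = 2 each, exact permutation p = 0.33). Differentiating oligodendrocyte-like nuclei, marked by genes such as Bcas1 and Enpp6, were 0.793% ± 0.411 in WT and 1.30% ± 0.171 in KO (n = 2 each, exact permutation p = 0.33). Shares of OPC-like nuclei (1.94% ± 0.217 and 1.78% ± 0.0937) and astrocyte-like nuclei (1.6% ± 0.410 and 1.34% ± 0.446) overlapped between groups (n = 2 each, exact permutation p = 0.667 for both). Neuron classes together held 56.4% of nuclei in each group. This depended on the floor: at 500 UMIs they held 44.8% ± 3.15 in WT and 40.4% ± 0.369 in KO, with 17.4% ± 5.12 and 26.8% ± 1.62 in unnamed low-UMI barcodes (n = 2 each, exact permutation p = 0.33 for both). Among nuclei outside the neuron classes, microglia-like nuclei were 25.1% ± 3.97 in WT and 33.2% ± 0.448 in KO, and oligodendrocyte-like nuclei 55.8% ± 4.93 and 46.9% ± 0.301. The smallest p these 4 libraries allow is 0.33, so these differences could not pass 0.05. By edgeR on nuclei counts, the log2 fold change was 0.40 in microglia-like nuclei (adjusted p = 0.554) and −0.25 in oligodendrocyte-like nuclei (edgeR adjusted p = 0.554). Without single libraries the difference ran from 2.13 points (without WT replicate 1) to 4.93 points (without WT replicate 2) in microglia-like nuclei, from −4.99 to −2.75 points in oligodendrocyte-like nuclei, and from 0.214 points (without WT replicate 1) to 0.796 points in differentiating oligodendrocyte-like nuclei. At a floor of 500 UMIs the differences were 1.58 points in microglia-like and −5.58 points in oligodendrocyte-like nuclei. At a floor of 2000 UMIs the libraries of both groups overlapped, with microglia-like nuclei at 5.52% and 7.65% in WT and 11.6% and 7.27% in KO, and oligodendrocyte-like nuclei at 13.1% and 16.6% in WT and 16.5% and 11.1% in KO. DAPI and propidium iodide sorting, the recovery of nuclei and the section of tissue dissected can also set these shares. Clusters of neurons differed too, chosen here after their values were seen: an excitatory cluster led by Tshz2 held 0.495% ± 0.25 of nuclei in WT and 2.28% ± 0.334 in KO, and one with Rorb among its leading genes 4.705% ± 0.0199 and 3.30% ± 0.579 (n = 2 each, exact permutation p = 0.33 for both).

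**Figure D2:**
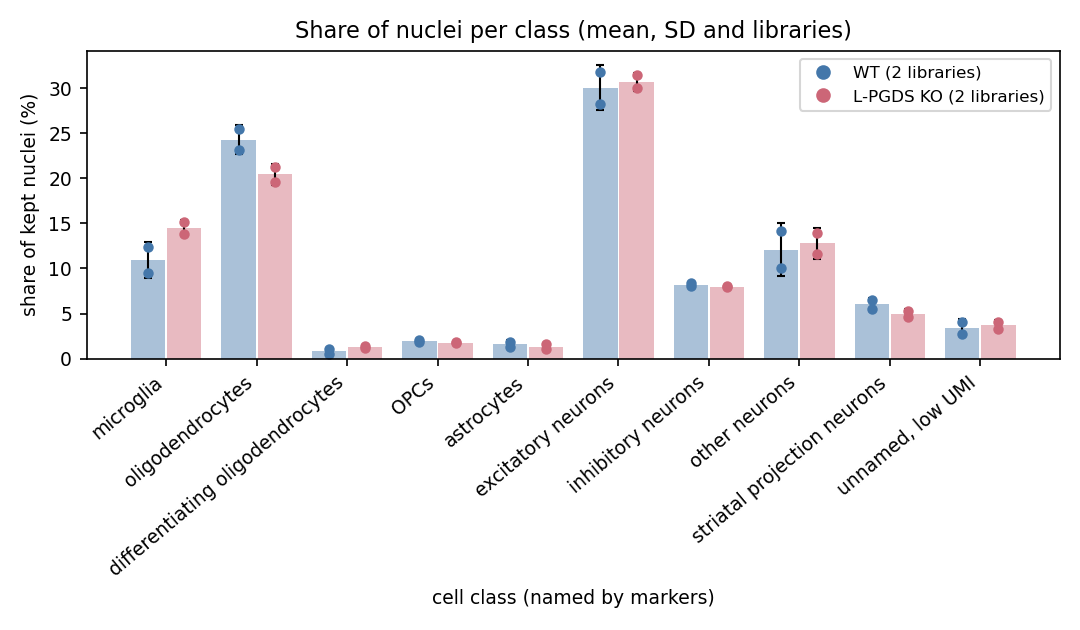
Share of kept nuclei (percent) in each class for WT and KO libraries; points are libraries and bars are group means with their SD. Microglia-like nuclei averaged 10.95% in WT and 14.5% in KO, and oligodendrocyte-like nuclei 24.3% and 20.4%.

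Immune nuclei separated into 8 sub-clusters, of which the largest had Ikbke, Hpse, Ctse and Gpnmb among its leading genes and was left unnamed. It held 29.0% ± 8.13 of immune nuclei in WT and 39.8% ± 0.742 in KO, a difference of 10.7 points. Homeostatic-like nuclei, with Tmem119 and Siglech among their leading genes, held 35.2% ± 4.25 in WT and 25.8% ± 1.08 in KO, a difference of −9.43 points. The libraries of both groups were separate for these 2 sub-clusters (n = 2 each, exact permutation p = 0.33, the smallest possible). Without single libraries their differences ran from 4.99 points (without WT replicate 1) to 16.5 points (without WT replicate 2), and from −12.4 to −6.42 points. At a floor of 2000 UMIs they were 3.97 and −4.44 points. The libraries then overlapped for the unnamed sub-cluster, at 24.8% and 33.9% in WT and 37.0% and 29.7% in KO (n = 2 each, exact permutation p = 0.667). Disease-associated-like nuclei, which carry genes microglia switch on around damaged myelin, held 24.9% ± 0.0793 in WT and 25.3% ± 1.58 in KO (n = 2 each, exact permutation p = 1). At 2000 UMIs they held 30.9% and 27.8% in WT and 32.8% and 34.1% in KO (n = 2 each, exact permutation p = 0.33). The difference was 4.10 points there, −1.07 at 1000 UMIs and −0.465 at 500 UMIs. On disease-associated genes the unnamed sub-cluster had a z score of 0.598, against 1.30 in disease-associated-like nuclei. Its normalized Apoe level was 140, against 115 in those. The disease-associated-like share therefore does not count all nuclei with such genes. Interferon-like nuclei were 5.28% ± 3.82 in WT and 3.49% ± 0.520 in KO, with 7.99% and 2.58% in the WT libraries. The sub-cluster carrying neuron transcripts held 2.15% ± 0.0905 in WT and 4.0% ± 1.56 in KO, and that carrying oligodendrocyte transcripts 1.53% ± 0.444 and 0.414% ± 0.233. None of the listed state genes passed the threshold over all genes between groups in microglia-like nuclei.

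In microglia-like nuclei, 3 of 12191 genes passed the threshold: Nrg1 was higher in KO, and Ptgds and the predicted gene Gm47283 were lower. Nrg1 (ENSMUSG00000062991; chromosome 8, 31814551 to 32884029), which encodes the growth factor neuregulin 1, rose from 113 ± 7.27 CPM in WT to 223.5 ± 35.0 in KO (n = 2 each), a log2 fold change of 0.98 (SE 0.15, edgeR adjusted p = 0.0428). Kcnq5 (0.81), Adgrb3 (0.78), Lrrtm4 (0.78) and Kcnip4 (0.60), genes of neuronal channels and synaptic adhesion, had the next smallest p among higher genes, with adjusted p from 0.151 to 0.282. Among lower genes these were Mmp12, a macrophage elastase, at −1.35 and Bank1 at −1.12 (adjusted p = 0.127 for both), then Vps9d1 at −0.81 and Malat1 at −0.32. The 6 tested markers of excitatory neurons were all higher in KO microglia-like nuclei (median log2 fold change 0.36, camera adjusted p = 0.0425, adjusted p = 0.486 with an estimated correlation). At an unadjusted p under 0.05 there were 862 genes. Leaving out single libraries changed the count past the threshold, which was highest without KO replicate 2. Nrg1 kept its call in 9 of 17 alternatives (adjusted p from 1.53e-09 to 0.921); its log2 fold change was 0.07 with doublets kept, 0.65 at a floor of 500 UMIs, and 0.73 without the sub-clusters that carried neuron or oligodendrocyte transcripts. In other glia Nrg1 was at 0.89 (SE 0.29) in astrocyte-like, 0.49 (SE 0.17) in oligodendrocyte-like, 0.10 (SE 0.17) in OPC-like and −0.53 (SE 0.31) in differentiating oligodendrocyte-like nuclei, none past the threshold. By the interaction test in edgeR no difference passed between its effect in microglia-like nuclei and that in astrocyte-like (−0.14, adjusted p = 1), oligodendrocyte-like (−0.49, adjusted p = 0.563) or OPC-like nuclei (−0.85, adjusted p = 0.107), given as the other class minus microglia-like nuclei. In empty droplets Nrg1 was at 0.55 (SE 0.13), and neuron markers put the share of free RNA in microglia-like nuclei at 16.4% and 17.6% in WT and 18.4% and 22.5% in KO. Subtraction at these shares left 0 of 120 and 0 of 200 Nrg1 counts in WT and 21 of 401 and 20 of 378 in KO.

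Disease-associated microglia genes ranked above other genes in KO microglia-like nuclei, with 20 of 23 members higher and a median log2 fold change of 0.29 (camera adjusted p = 6.16e-06, adjusted p = 0.678 with an estimated correlation). Apoe, the main lipid carrier of glia, stood at 5986 ± 1088 CPM in WT and 11406 ± 6068 in KO (n = 2 each), with 15697 and 7115 CPM in the KO libraries. None of the 23 passed over all genes, and 3 passed adjusted over the list alone. The members with the smallest p were Apoe (0.95, SE 0.24), Cst7, a cathepsin inhibitor (1.00, SE 0.28), Igf1 (0.51) and the protease Ctsl (0.62). Of lipid handling genes, 15 of 21 were higher (camera adjusted p = 0.00404, adjusted p = 0.678 with an estimated correlation), among them the cholesterol exporters Abca1 (0.46) and Abcg1 (0.49) and the apolipoprotein Apoc1 (1.13); 1 passed adjusted over the list alone. Complement and phagocytosis genes had 14 of 18 members higher (camera adjusted p = 0.0319, adjusted p = 0.678 with an estimated correlation), led by Fcgr2b (0.44) and Axl (0.28). All 26 ribosomal protein genes were higher (median 0.43, camera adjusted p = 5.67e-15, adjusted p = 0.678 with an estimated correlation), 11 of them past the threshold adjusted over the list alone, with Rps3 at 0.89 and Rpl32 at 0.63. All 11 mitochondrial transcripts were also higher (median 0.26, camera adjusted p = 4.77e-04, adjusted p = 0.678 with an estimated correlation). The disease-associated oligodendrocyte list, which includes the class I antigen presentation genes B2m (0.59), H2-D1 (0.40) and H2-K1 (0.35), none of them past the threshold over all genes, had 7 of 8 members higher (camera adjusted p = 0.0181, adjusted p = 0.678 with an estimated correlation). In empty droplets the disease-associated list had 20 of 23 members higher in KO (median log2 ratio 0.31), and Apoe stood at 3808 CPM in WT and 4999.6 in KO.

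Homeostatic microglia genes did not pass in microglia-like nuclei (camera adjusted p = 0.379), with 8 of 14 members higher, a median of 0.02 and a mean of −0.09, which differ in sign. Crybb1 was at −1.21 (SE 0.38) and Siglech at −0.25 (SE 0.13). Proliferation genes had a median of −0.17 (camera adjusted p = 0.0560), with Top2a, a topoisomerase of dividing cells, at −0.98 (SE 0.25). Neither interferon response genes (adjusted p = 0.740, 10 of 21 higher), antigen presentation genes (adjusted p = 0.203, 9 of 13 higher) nor cytokine and NF-kB genes (adjusted p = 0.740, 9 of 18 higher) passed; Tnf, an inflammatory cytokine, was at −1.29 (SE 0.36, adjusted p = 0.434). The prostaglandin pathway without Ptgds did not pass either (adjusted p = 0.509, 6 of 15 members higher), with the prostaglandin-degrading Hpgd at −0.26 and the cyclooxygenase Ptgs1 at −0.27.

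Over all immune nuclei, 2 of 12217 genes passed, Ptgds and Gm47283, both lower in KO, and 864 had an unadjusted p under 0.05. Nrg1 was at 0.98 (adjusted p = 0.0548) and Cd163, a marker of border macrophages, at −2.83 (SE 0.72, adjusted p = 0.256). The count was 6 without WT replicate 1, 4 without WT replicate 2, 86 without KO replicate 1 and 353 without KO replicate 2. Gene lists behaved much as in microglia-like nuclei, which make up nearly all of this population: 6 lists passed, with disease-associated genes at 20 of 23 higher (camera adjusted p = 5.48e-06) and proliferation genes at 4 of 13 higher (camera adjusted p = 0.0462). Both were lost with an estimated correlation (adjusted p = 0.735 with an estimated correlation).

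The authors' deposited table for immune nuclei lists 222 genes, 170 higher and 52 lower in KO, of which 5 had an adjusted p under 0.05. In the authors' deposited table these were Gm42418 (0.78, adjusted p = 0.00497), Chsy3, Fut9 and Sh3gl2, which it lists at 0 in both WT libraries, and Gm47283 (−1.90, adjusted p = 0.0189). Counts summed here over all immune nuclei were above 0 in WT for these 3 genes, at 43.9 ± 7.89 CPM in WT and 63.1 ± 12.6 in KO for Chsy3, 30.9 ± 7.13 and 60.2 ± 25.1 for Fut9, and 26.4 ± 5.90 and 49.6 ± 9.48 for Sh3gl2 (n = 2 each). Their log2 fold changes here were 0.50, 0.91 and 0.87 (edgeR adjusted p = 0.663, 0.539 and 0.461). The next genes by adjusted p in the authors' deposited table were Il1rapl2, Gnal, Rasgrf1 and Gap43 among higher genes, and Sez6l2 among lower ones. The authors' deposited table also holds Cst7, Ctsl and Igf1 of the disease-associated list, Abca1, B2m, Il6, Tmem163 and 9 ribosomal protein genes as higher, and Top2a and the mitochondrial transcript mt-Nd2 as lower, and it does not list Ptgds. Over all immune nuclei here mt-Nd2 was at 0.16 (SE 0.16, edgeR adjusted p = 0.887), opposite in sign to that table. Of its genes, 206 could be tested over all immune nuclei here and 200 of these (97.1%) had the same sign, with a Spearman correlation of 0.558 across genes, which are not independent replicates. An unadjusted p under 0.05 was found here for 126 of them and an adjusted p under 0.05 for 1. Both sets of values come from the same libraries and are not independent evidence.

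In oligodendrocyte-like nuclei, 2 of 12766 genes passed, Ptgds and Gm47283, both lower in KO, and 819 had an unadjusted p under 0.05. The genes with the next smallest p were, among higher genes, Hmga2 (1 and 3 counts in WT, 21 and 15 in KO), Lrmda (0.84, SE 0.15), the neuropeptide gene Cartpt (1.79), the complement gene C1qb (0.85) and Tenm2 (0.69). Among lower genes they were Polr3e (−0.98, adjusted p = 0.159), the hypothalamic neuropeptide gene Pmch (−3.16), the heat shock gene Hspa1a (−1.97) and Psmg2 (−0.77). The count was 10 without WT replicate 1, 65 without WT replicate 2, 2 without KO replicate 1 and 124 without KO replicate 2.

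Gene lists of microglia ranked high in KO oligodendrocyte-like nuclei. Of disease-associated microglia genes, 18 of 19 were higher (median log2 fold change 0.60, camera adjusted p = 4.80e-13, adjusted p = 0.523 with an estimated correlation), none passed over all genes and 9 passed adjusted over the list alone, with Cst7 at 2.25 (SE 0.55), Tyrobp at 1.07 (SE 0.25), Apoe at 0.71 (SE 0.20) and Spp1 at 0.90 (SE 0.27). Complement genes had 8 of 9 members higher (median 0.61, camera adjusted p = 1.29e-07, adjusted p = 0.523 with an estimated correlation), with C1qb at 0.85 and Fcer1g at 1.21, and markers of microglia 8 of 11 (camera adjusted p = 5.11e-05, adjusted p = 0.245 with an estimated correlation). Lipid handling (14 of 19 higher, adjusted p = 5.49e-04), antigen presentation (6 of 7, adjusted p = 0.00133), homeostatic microglia (8 of 11, adjusted p = 0.00724) and disease-associated oligodendrocyte genes (9 of 11, adjusted p = 0.00394) also passed camera, with B2m at 1.00 (SE 0.25) and the protease Klk6 at 0.83. These 4 were lost with an estimated correlation (adjusted p = 0.523 with an estimated correlation for each). So did reactive astrocyte genes (10 of 10 higher, adjusted p = 0.00331), mitochondrial transcripts (11 of 11, adjusted p = 5.16e-05), ribosomal protein genes (24 of 26, adjusted p = 8.34e-04) and OPC markers (7 of 7, adjusted p = 2.57e-04, adjusted p = 0.245 with an estimated correlation). The others were at adjusted p = 0.523 with an estimated correlation, but ribosomal protein genes at adjusted p = 0.697 with an estimated correlation. Immediate early and handling stress genes ranked low, with 2 of 11 higher (adjusted p = 0.00483) and Hspa1a, Jun (−0.50) and Fos (−0.92) among them, as did cytokine and NF-kB genes (1 of 6 higher, adjusted p = 0.0424). Both were lost with an estimated correlation (adjusted p = 0.523 with an estimated correlation). In empty droplets, microglia markers were also higher in KO (9 of 12, median log2 ratio 0.26), as were complement genes (17 of 20, median 0.30), while immediate early genes were lower (1 of 14 higher, median −0.42). Myelin genes did not pass (14 of 19 higher, median 0.11, camera adjusted p = 0.133), with Trf at 0.36 and Ermn at −0.40, and neither did cholesterol synthesis genes (15 of 19 higher, camera adjusted p = 0.0606), the integrated stress response (8 of 16 higher, adjusted p = 0.835) or the prostaglandin pathway without Ptgds (3 of 11 higher, adjusted p = 0.710).

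In OPC-like nuclei, the precursors that renew oligodendrocytes, 7 of 7478 genes passed, 4 higher and 3 lower in KO. Zfp804b (ENSMUSG00000092094; chromosome 5, 6769010 to 7344756) rose from 54.3 ± 4.08 CPM in WT to 187 ± 77.1 in KO (n = 2 each; log2 fold change 1.83, SE 0.31, edgeR adjusted p = 0.00494). The cell adhesion gene Cntn5 (ENSMUSG00000039488; chromosome 9, 9660891 to 10904775) rose from 49.7 ± 14.4 to 181 ± 99.6 CPM (1.81, SE 0.35, adjusted p = 0.0243). The predicted genes Gm42418 and Gm32647 were also higher, the latter with 77 of its KO counts in KO replicate 1 and 14 in KO replicate 2. The nuclear RNA Malat1 (ENSMUSG00000092341; chromosome 19, 5795690 to 5802672) fell by 0.31 on the log2 scale (SE 0.05, adjusted p = 0.00697), and Ptgds and Gm47283 were lower. The class held 125 and 117 nuclei in WT and 105 and 99 in KO, and 459 genes had an unadjusted p under 0.05. DESeq2 called 0 genes, with 58 at an unadjusted p under 0.05. The edgeR count was 12 without WT replicate 1, 19 without WT replicate 2, 16 without KO replicate 1 and 80 without KO replicate 2. Zfp804b kept its call in 11 of 16 alternatives (adjusted p from 1.98e-11 to 0.837) and Cntn5 in 10 of 15 (from 5.34e-11 to 0.667); with doublets kept they were at 0.87 and 1.30. Without single libraries Zfp804b ran from 1.28 (without KO replicate 1, adjusted p = 0.0711) to 2.16, and Cntn5 from 1.15 (without KO replicate 2) to 2.32 (without KO replicate 1). Malat1 kept its call in 12 of 16 alternatives, from −0.44 to −0.20.

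All 5 tested proliferation genes were lower in KO OPC-like nuclei, with a median log2 fold change of −1.57 (camera adjusted p = 2.12e-08, adjusted p = 0.283 with an estimated correlation). None passed over all genes and 4 passed adjusted over the list alone, with Top2a at −1.57 (SE 0.39) and Diaph3 at −0.59 (SE 0.27). The mitotic gene Kif15 held 12 and 15 counts in WT and 1 in each KO library. The kinetochore gene Knl1 held 17 and 16 counts in WT and 3 and 1 in KO. Both genes passed the count filter through their WT counts alone, and the untested members of the list did not pass it. That all 5 were lower therefore rests in part on the filter. Disease-associated oligodendrocyte genes were higher in 6 of 6 (median 0.94, camera adjusted p = 1.17e-04, adjusted p = 0.283 with an estimated correlation), with the complement gene C4b at 1.25 (SE 0.46) and the class I antigen presentation genes H2-D1 at 0.95, B2m at 0.94 and H2-K1 at 1.11. Disease-associated microglia genes were higher in 7 of 7 (median 0.69, camera adjusted p = 4.37e-05, adjusted p = 0.407 with an estimated correlation), with Apoe at 0.69 (SE 0.18) and Ctsb at 0.89. Complement genes were higher in 5 of 5 (adjusted p = 3.06e-04, adjusted p = 0.283 with an estimated correlation), with C1qb at 1.46 and C1qa at 1.42. Lipid handling (9 of 10 higher, adjusted p = 0.0215, adjusted p = 0.407 with an estimated correlation) and ribosomal protein genes (23 of 26, adjusted p = 0.00186, adjusted p = 0.488 with an estimated correlation) passed camera too. Microglia markers were higher in 6 of 6 in the same nuclei (camera adjusted p = 1.09e-05, adjusted p = 0.528 with an estimated correlation). Differentiation genes did not pass (5 of 10 higher, adjusted p = 0.615; Gpr17 at 0.32, SE 0.29), nor did the prostaglandin pathway (2 of 5 higher, adjusted p = 0.600).

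In astrocyte-like nuclei, 2 of 5796 genes passed: the potassium channel gene Kcnq5 was higher in KO and Ptgds was lower. Kcnq5 (ENSMUSG00000028033; chromosome 1, 21398403 to 21961942) rose from 76.7 ± 24.0 CPM in WT to 419 ± 144 in KO (n = 2 each; log2 fold change 2.48, SE 0.33, edgeR adjusted p = 0.00152). The genes with the next smallest p were Sgcz (1.83, SE 0.35, adjusted p = 0.0562), Lrrtm4 (1.93), Lingo2 (1.45) and Dpp10 (1.73) among higher genes. Among lower genes they were the serotonin receptor gene Htr2c (−2.38, SE 0.54, adjusted p = 0.121), Utp14a (−2.80), Pnn (−1.48) and Ctnnal1 (−1.61). Markers of neurons of any type were higher in 5 of 5 in these nuclei (median 0.73, camera adjusted p = 0.00187, adjusted p = 0.409 with an estimated correlation). Neuron markers put the share of free RNA at 16.8% and 19.2% in WT and 32.6% and 21.6% in KO. In empty droplets Kcnq5 was at 0.48 (SE 0.14), with 419 and 555 CPM in WT. At these shares free RNA was expected above the 59.7 and 93.7 CPM of Kcnq5 measured in WT astrocyte-like nuclei. Subtraction therefore left no WT counts of Kcnq5, and its call after subtraction does not test a change in this class. Disease-associated microglia genes were higher in 8 of 8 (median 0.51, camera adjusted p = 0.00247), with the protease Ctsd at 1.09 (SE 0.35) and Apoe at 0.66 (SE 0.21), and mitochondrial transcripts in 10 of 11 (median 0.46, adjusted p = 0.00247). Both were lost with an estimated correlation (adjusted p = 0.629 with an estimated correlation). Homeostatic astrocyte genes did not pass (9 of 12 higher, adjusted p = 0.101), with the potassium channel gene Kcnj10 at 0.72 (SE 0.27) and Glul, which makes glutamine, at −0.42. The class held 113 and 86 nuclei in WT and 94 and 59 in KO. The count of genes was 26 without WT replicate 1, 19 without WT replicate 2, 31 without KO replicate 1 and 78 without KO replicate 2, and Kcnq5, called in 12 of 16 alternatives, was at 0.87 with doublets kept (adjusted p = 0.465; range over its alternatives 9.81e-14 to 0.541).

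**Figure D3:**
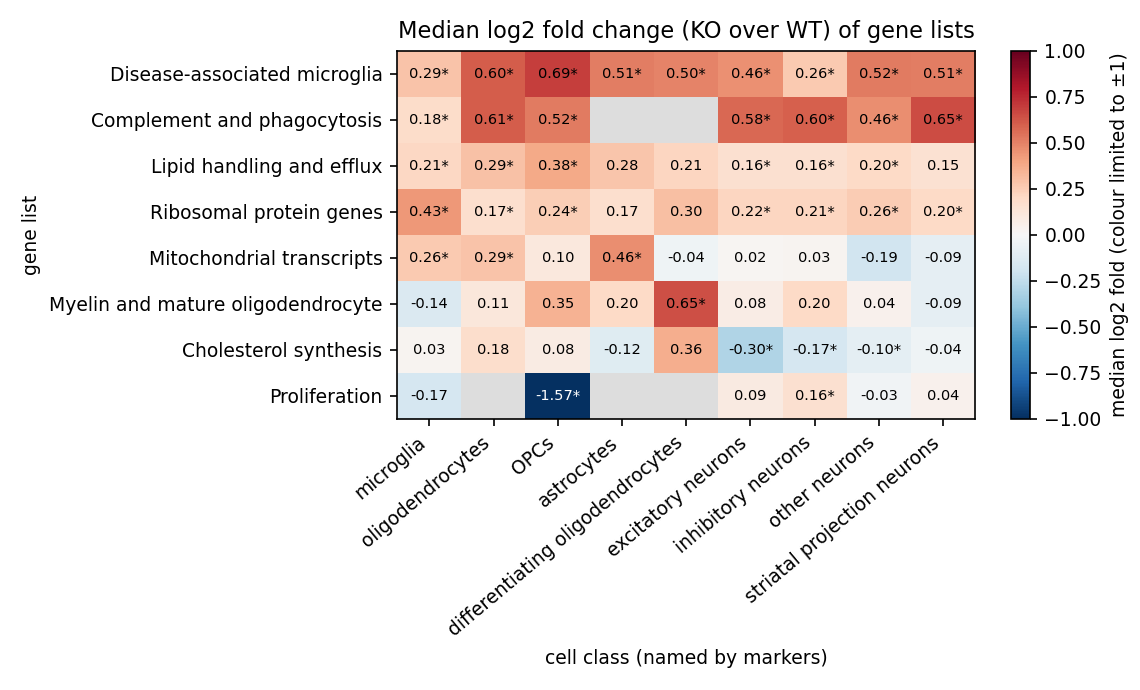
Median log2 fold change (KO over WT) of 8 of the fixed gene lists (vertical axis) in each class of nuclei (horizontal axis), shown by colour and in figures, with grey where under 5 members were tested; stars mark camera adjusted p under 0.05 at the preset correlation. Disease-associated microglia genes had positive medians in the 4 main glial classes (0.29 in microglia-like, 0.60 in oligodendrocyte-like, 0.69 in OPC-like and 0.51 in astrocyte-like nuclei). Each starred call was lost with an estimated correlation (adjusted p = 0.678, 0.523, 0.407 and 0.629 with an estimated correlation for these 4 medians). Disease-associated microglia genes also had a positive median in excitatory neurons and, outside the figure, in empty droplets (log2 ratio 0.31).

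Across further classes, 12 calls were made, of which 5 were Ptgds. With RLE instead of TMM scaling there were 8, as inhibitory neurons lost both calls (836 genes at an unadjusted p under 0.05) and striatal projection neurons kept 2 of 4. In a group of other neurons, Bnc2 (ENSMUSG00000028487; chromosome 4, 84275095 to 84675275), a zinc finger gene, rose from 25.1 ± 2.86 to 54.6 ± 2.83 CPM (n = 2 each; log2 fold change 1.13, SE 0.13, edgeR adjusted p = 0.0365). Pmch (ENSMUSG00000035383; chromosome 10, 88091072 to 88092375), the precursor of melanin-concentrating hormone of hypothalamic neurons, fell from 26.0 ± 3.71 to 1.93 ± 1.83 CPM in these nuclei (−3.73, SE 0.45, adjusted p = 0.0297). Without KO replicate 1 Pmch was at −5.28 and without KO replicate 2 at −3.01. In empty droplets Pmch stood at 80.5 and 70.8 CPM in WT and at 56.3 and 6.80 CPM in KO, and Hcrt, another hypothalamic neuropeptide gene, at 48.3 and 16.4 CPM in WT and 6.99 and 1.26 CPM in KO. The section of tissue dissected can set the level of such genes, and this was not separated from an effect of the KO. Excitatory neurons, inhibitory neurons and differentiating oligodendrocyte-like nuclei gave no further named gene past the threshold. These counts also rested on single libraries, and the highest came without KO replicate 2, where the KO group is a lone library.

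Values of Gm47283, Gm42418 and Malat1 are given here class by class. Gm47283 (ENSMUSG00000096768; chromosome Y, 90784738 to 90816464) was lower in KO in all 9 tested classes and in empty droplets, with log2 fold changes from −2.44 to −1.99. In microglia-like nuclei it stood at 333 ± 45.9 CPM in WT and 78.6 ± 52.3 in KO (n = 2 each; −2.12, SE 0.28, edgeR adjusted p = 0.00957), with 41.6 and 116 CPM in the KO libraries. Gm21887 (ENSMUSG00000095562; chromosome X, 170009659 to 170019281), which lies with Gm47283 in the region shared by both sex chromosomes, passed the threshold in striatal projection neurons (−2.49, SE 0.49, adjusted p = 0.0446), and reads of such near-identical copies are of uncertain origin. Gm42418 (ENSMUSG00000098178; chromosome 17, 39846958 to 39848788), a gene model overlapping a ribosomal RNA repeat, was higher in KO, at 0.76 in OPC-like nuclei (SE 0.11, adjusted p = 0.00202), from 0.67 to 0.82 in 8 other classes, and at 0.40 (SE 0.32) in empty droplets. Malat1 was at −0.32 (SE 0.08) in microglia-like, −0.31 (SE 0.18) in oligodendrocyte-like and −0.35 (SE 0.10) in astrocyte-like nuclei, none of them past the threshold. It was at −0.30 in excitatory, −0.20 in inhibitory, −0.14 in striatal projection and −0.09 in other neurons, at 0.13 (SE 0.33) in differentiating oligodendrocyte-like nuclei, and at −0.49 (SE 0.32) in empty droplets. These genes were chosen after their values were seen, apart from Malat1.

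**Figure D4:**
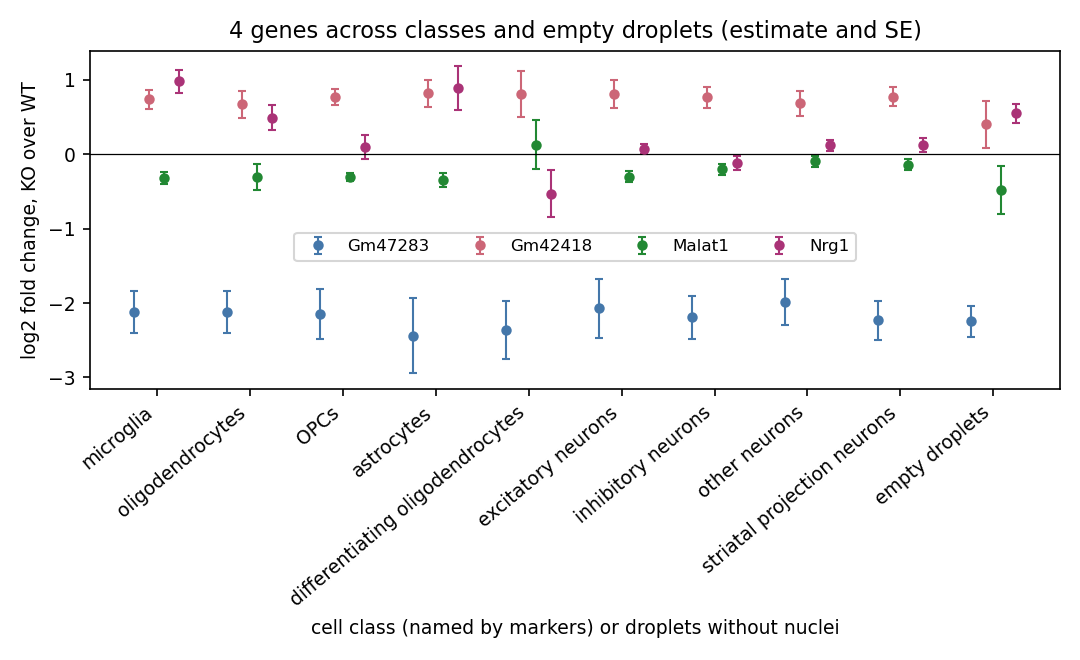
Log2 fold change (KO over WT, vertical axis) with its SE for Gm47283, Gm42418, Malat1 and Nrg1 in each class of nuclei and in empty droplets (horizontal axis). Gm47283 lies between −2.44 and −1.99 in each class, and Nrg1 is at 0.98 in microglia-like, 0.89 in astrocyte-like, 0.49 in oligodendrocyte-like, 0.10 in OPC-like and −0.53 in differentiating oligodendrocyte-like nuclei, 0.55 in empty droplets and 0.07 in excitatory neurons.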

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

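The tests of differences between classes were run and adjusted over all genes tested in each pair of classes. The results given gene by gene here are for genes already named in the report, chosen after their values had been seen. The KO effect on 6 of these genes differed between astrocyte-like nuclei and another class by the interaction test in edgeR. For the potassium channel gene Kcnq5, the log2 effect in astrocyte-like nuclei minus that in microglia-like nuclei was 1.62 (adjusted p = 0.00593), minus that in oligodendrocyte-like nuclei 2.12 (adjusted p = 4.24e-08), and minus that in OPC-like nuclei 2.33 (adjusted p = 2.70e-05). For the serotonin receptor gene Htr2c, the effect in astrocyte-like nuclei was lower, by −3.46 against microglia-like nuclei (adjusted p = 1.46e-14) and by −2.37 against oligodendrocyte-like nuclei (adjusted p = 4.84e-09). The effect on the synaptic adhesion gene Lrrtm4 was higher by 1.42 than in oligodendrocyte-like nuclei (adjusted p = 0.00429) and by 1.89 than in OPC-like nuclei (adjusted p = 4.76e-04). Against OPC-like nuclei, the effect in astrocyte-like nuclei was also higher for Lingo2 by 1.87 (adjusted p = 0.00125), for Dpp10 by 1.74 (adjusted p = 0.00548) and for Sgcz by 1.73 (adjusted p = 0.00110). Neuron RNA in astrocyte-like nuclei was not separated from the higher effects. The lower effect on Htr2c runs opposite to the rise of neuron markers there. At resolution 1.6 and at a floor of 2000 UMIs, Htr2c was among the leading genes of a cluster of other neurons. A change in the kind of neuron RNA was therefore not excluded, and the cause of the lower effect was not tested. Markers of neurons of any type were higher in 5 of 5 in KO astrocyte-like nuclei (median 0.73, camera adjusted p = 0.00187, adjusted p = 0.409 with an estimated correlation). Neuron markers put the share of free RNA there at 16.8% and 19.2% in WT and 32.6% and 21.6% in KO. With doublets kept Kcnq5 was at 0.87 in astrocyte-like nuclei (adjusted p = 0.465), against 2.48 as reported. Over all genes tested, the effect differed for 16 genes between OPC-like and astrocyte-like nuclei, 11 between oligodendrocyte-like and astrocyte-like nuclei, 10 between microglia-like and oligodendrocyte-like nuclei, 5 between microglia-like and astrocyte-like nuclei and 3 between microglia-like and OPC-like nuclei. Between oligodendrocyte-like and OPC-like nuclei it differed for 0 of 12486 genes by edgeR, with 602 at an unadjusted p under 0.05, and no other tool was run. No group held enough libraries for a test of outlying samples.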

How the results depend on the processing

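The floors of 500 and 2000 UMIs, the subtraction of the empty-droplet profile and the removal of mixed immune sub-clusters were chosen after seeing the data; the other settings were planned. Each group has 2 libraries, and leaving 1 out leaves a lone sample assumed to vary like the other group. The KO libraries differed more from each other than the WT libraries (chi-square over degrees of freedom 18.9 and 7.23). Counts of changed genes without a KO library leave out that larger spread and can be too high. The lower Ptgds level over all nuclei kept its direction and call in all 8 alternatives, from −4.43 to −3.56 without single libraries. The higher share of microglia-like nuclei and the lower share of oligodendrocyte-like nuclei kept their direction in all 11 alternatives each, from 2.13 to 4.93 and from −4.99 to −2.75 points without single libraries. At 500 UMIs these differences were 1.58 and −5.58 points, and at 2000 UMIs, where the libraries of both groups overlapped, 2.83 and −1.06 points. All neuron classes together differed by 0.0442 points as reported and by −4.37 points at 500 UMIs. Without single libraries the unnamed immune sub-cluster 0 ran from 4.99 to 16.5 points and homeostatic-like nuclei from −12.4 to −6.42 points. At 2000 UMIs these 2 differences were 3.97 and −4.44 points, and the libraries of both groups overlapped for sub-cluster 0. Unless stated otherwise, the cause was not tested.

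Counts of changed genes are given for microglia-like, oligodendrocyte-like, OPC-like, astrocyte-like and all immune nuclei (3, 2, 7, 2 and 2 as reported) and for further classes (12). DESeq2 gave 1, 1, 0, 1 and 1, with 58 genes at an unadjusted p under 0.05 in OPC-like nuclei. No filter on low counts gave 107, 52, 22, 33 and 92, and 347 in further classes. With the replicate number as a block the counts were 85, 66, 24, 13 and 65, and 67 in further classes; the numbers did not pair the samples, with correlations of same-numbered deviations of 0.00768, 0.112, 0.0276, −0.0588 and 0.0102. A floor of 1000 UMIs gave 1 in microglia-like and 1 in all immune nuclei. Doublets kept gave 1 in microglia-like, 2 in OPC-like and 1 in all immune nuclei. Mitochondrial UMIs under 1% gave 5 in microglia-like, 20 in OPC-like, 17 in astrocyte-like and 5 in all immune nuclei. Equal nuclei per library gave 10 in astrocyte-like and 5 in all immune nuclei. In astrocyte-like nuclei edgeR gave 0 at resolution 1.6, at 500 UMIs and at 2000 UMIs, with 379, 415 and 305 genes at an unadjusted p under 0.05. In OPC-like nuclei 500 UMIs gave 3. At 2000 UMIs oligodendrocyte-like nuclei gave 1 and all immune nuclei 4. RLE scaling gave the same genes in these 5 populations and 8 calls in further classes. After subtraction microglia-like nuclei gave 4, none of them among the 3 reported; OPC-like nuclei gave 4, 1 of them reported (Zfp804b); astrocyte-like nuclei gave 2, 1 reported (Kcnq5); all immune nuclei gave 2 and further classes 4, of which only Pmch was reported. Oligodendrocyte-like nuclei gave 0 by edgeR (469 at an unadjusted p under 0.05). Ptgds was called in no class after subtraction. For Kcnq5 in astrocyte-like nuclei the subtracted level exceeded the whole WT level, so its call there does not test a change. Leaving out single libraries gave 4 to 366 in microglia-like, 2 to 124 in oligodendrocyte-like, 12 to 80 in OPC-like, 19 to 78 in astrocyte-like and 4 to 353 in all immune nuclei, and 39 to 1922 in further classes. The highest count came without KO replicate 2 in each case.

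Gene lists passing camera (6, 11, 6, 2 and 6 as reported) numbered 0 in all 5 populations with an estimated correlation and 0 with fry. After subtraction 2 lists passed in OPC-like and 1 in astrocyte-like nuclei. Without single libraries 4 to 8 lists passed in microglia-like, 4 to 10 in oligodendrocyte-like, 4 to 8 in OPC-like, 0 to 4 in astrocyte-like and 4 to 8 in all immune nuclei. The authors' deposited table holds 1 gene at an adjusted p under 0.01. Share differences that changed sign were excitatory neurons (0.652 as reported) and other neurons (0.679), at −2.08 and −0.616 with 500 UMIs, and disease-associated-like immune nuclei (0.392), at −1.07 with 1000 UMIs. Without single libraries these were −1.11 to 2.41, −1.39 to 2.75 and −0.723 to 1.51. So did astrocyte-like nuclei (−0.582 to 0.0491, above 0 without WT replicate 1 or KO replicate 2) and interferon-like nuclei (−4.49 to 0.913, above 0 without WT replicate 1).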

Other observations

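The tests on the neuron markers in microglia-like nuclei, on Gm47283 across populations, on the summed sex chromosome copies and on Gm42418 in other classes were chosen only after the results had been seen, as were the removal of mixed sub-clusters and the subtraction of free RNA. In differentiating oligodendrocyte-like nuclei, all 18 tested myelin genes were higher in KO (median log2 fold change 0.65, camera adjusted p = 5.27e-09, adjusted p = 0.362 with an estimated correlation). None passed over all genes and 1 passed adjusted over the list alone. Oligodendrocyte markers were higher in 12 of 12 (median 0.77, camera adjusted p = 3.23e-07) and OPC markers in 1 of 6 (median −0.99, camera adjusted p = 1.27e-04), both with adjusted p = 0.275 with an estimated correlation. WT replicate 1 held 30 nuclei of this class and the other libraries 67 to 82.

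In excitatory neurons, 19 of 20 cholesterol synthesis genes were lower in KO (median log2 fold change −0.30, camera adjusted p = 5.50e-10, adjusted p = 0.424 with an estimated correlation). The same list was lower in 13 of 19 members in inhibitory neurons (median −0.17, adjusted p = 0.0284, adjusted p = 0.441 with an estimated correlation) and in 16 of 20 in other neurons (median −0.10, adjusted p = 0.0114, adjusted p = 0.312 with an estimated correlation). None of these genes passed over all genes, and 1 passed adjusted over the list alone, in inhibitory neurons. In empty droplets all 20 members were lower as well (median log2 ratio −0.20). Integrated stress response genes were higher in 13 of 13 in other neurons (median 0.41, camera adjusted p = 5.31e-04, adjusted p = 0.312 with an estimated correlation). Disease-associated microglia genes were higher in 20 of 21 in excitatory neurons (median 0.46, camera adjusted p = 9.10e-13, adjusted p = 0.424 with an estimated correlation), where microglia markers were higher in 9 of 11. In empty droplets Cst7 stood at 13.4 ± 2.86 CPM in WT and 34.3 ± 10.3 in KO, Tyrobp at 107 ± 10.6 and 172 ± 13.2, and B2m at 136 ± 42.2 and 258 ± 11.7 (n = 2 each).

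Nrg1 was higher in KO microglia-like nuclei by 0.98 on the log2 scale, and stood at 0.89 in astrocyte-like, 0.49 in oligodendrocyte-like, 0.10 in OPC-like and −0.53 in differentiating oligodendrocyte-like nuclei. An even rise of neuron RNA of any origin is argued against, since the median over 22 neuron markers in these nuclei was 0.22 (upper quartile 0.38), below that change. This covers only a rise that is even across neuron genes. In empty droplets Nrg1 rose more than markers of neurons of any type, which had 2 of 5 members higher and a median log2 ratio of −0.0043. Neuron RNA richer in Nrg1 was therefore not excluded. Free RNA and neuron fragments joined to microglia may still contribute, and neither can be told apart from a change in microglia. Nrg1 was higher in empty droplets by 0.55 (SE 0.13), and was at 0.73 without the mixed sub-clusters, values between no change and the whole of it. Subtraction of free RNA left 0 of 120 and 0 of 200 Nrg1 counts in WT and 21 of 401 and 20 of 378 in KO. At the estimated share, which overstated free RNA for Ptgds in WT, free RNA alone can carry nearly all Nrg1 counts in these nuclei. The counts left were too few to decide. An effect of L-PGDS loss on microglia stays open as a hypothesis, untested beyond these libraries.

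Gm47283 was lower in KO libraries in all 9 tested classes, and Gm21887 in the 6 classes where it was tested (−2.49 to −1.84). Fewer Y chromosome transcripts are argued against by the other Y-linked genes. The median of those genes over all nuclei was −0.066 and their lowest value −0.45 (SE 0.23, Eif2s3y, lower mainly in KO replicate 1). A move of reads from one copy to the other is argued against, since both were lower over all nuclei (−2.08 and −2.18). Their summed CPM (−2.07) had to fall with them and is no further test. Reads of Gm47283 and Gm21887 assigned elsewhere were not examined. A difference in copy number or sequence at their locus between the WT and KO mice is a candidate explanation, in line with a log2 fold change no higher than −1.99 in any class or in empty droplets. The KO libraries held 31.9 and 92.6 CPM of Gm47283 over all nuclei, against 232 and 289 CPM in WT, a spread that a difference fixed between WT and KO mice does not account for. An effect of L-PGDS loss itself was not separated from such a difference.

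Gm42418 was higher in KO OPC-like nuclei by 0.76. A change in these nuclei alone is argued against by the median of 0.77 over the 8 other tested classes. Ribosomal RNA pieces spread throughout the libraries may account for it, but this cannot be told apart from other causes because the log2 fold change in empty droplets, 0.40, had an SE of 0.32. An effect of L-PGDS loss on ribosomal RNA stays open and was not tested.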
